A study of Homo sapiens with 6 samples.

How the data were processed

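The series compares Huh-7 hepatoma cells transduced with a lentivirus for MIR517A and GFP (3 arrays) with cells that received GFP without the microRNA (3 arrays). Per the labels' protocols, virus was made in 293T cells, GFP-positive cells were sorted, total RNA was extracted with TRIzol and the labelled RNA carried biotin. The deposited table holds 1 intensity per probe set and array, read here as linear. RMA, a method that corrects background, normalizes between arrays and summarises probes into probe sets, is named in the submitters' processing notes, with no version and no setting; these are not given in the sources used here. RMA values are usually on a log2 scale, and the deposited intensities lie between 2.13 and 15746 (the latter on MIR517A 1), a range expected of linear intensities. They were taken as linear, and log2 was taken before any test, as had been foreseen. Whether the deposit holds another transformation is not known, and every log2 difference rests on this reading. The sorted intensities of the 6 arrays were close to each other but not identical. Medians per array were 87.8, 86.7 and 85.8 for GFP control 1 to 3 and 82.7, 84.6 and 83.7 for MIR517A 1 to 3. Scanner files, background measurements, detection calls and scan dates were not analysed here, so no probe set can be called present or absent and no batch could be tested.

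Genes were named through a table of the array's annotation. It listed 21214 of the 33297 probe sets. Of these, 19460 had 1 gene symbol, 1754 had several and were not used for genes, and the other 12083 probe sets were unnamed here. Symbols were compared with a RefSeq table of GRCh38.p14 through the gene identifiers; 19429 probe sets matched and 0 symbols had to be updated. The arrays gave 18417 genes, of which 769 had more than 1 probe set; the probe set with the highest mean log2 value stood for the gene. Control probe sets carry no name in these tables and were not told apart, so a planned check of RNA quality on control probe sets was not run. A planned test of genes with sites for the seed of the microRNA in their 3′ untranslated regions needs transcript sequence and was not run.

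Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without other covariates and without a filter on dim probe sets), and p-values were adjusted with Benjamini-Hochberg over all genes. A gene was called changed at an adjusted p under 0.05. The prior degrees of freedom were 4.98. Fold changes are ratios of intensities on the linear scale obtained from log2 differences, MIR517A minus GFP control. RMA subtracts background by a model and dim probe sets keep a floor of unspecific signal, so fold changes of dim genes can be understated. Background was not measured, and the size of changes of dim genes is uncertain. The 39 gene lists hold 711 entries, of which 653 were measured, and were tested with camera at a preset correlation between genes of 0.01 and, as an alternative, with an estimated correlation; each list's members were also adjusted over the list alone. Random lists (10000 per list), added after the data were seen, were drawn from 20 classes of brightness. Their genes were drawn independently of each other, so the percentiles ignore correlation between list members and the spread between arrays. Principal components separated the groups on the first axis, which held 55.5% of the variance, and 17.4% lay on the second. Pearson's correlation between arrays, across genes, which are not independent replicates, was at least 0.989.

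The genes named in the text follow a rule written before the data were examined. It takes the 12 largest rises and 12 largest falls among changed genes whose 3 MIR517A arrays all lie on 1 side of the 3 controls and whose higher group mean exceeds the median of all probe sets (6.41); chance alone separates 3 arrays from 3 arrays in 10% of genes. It adds up to 4 changed members, by smallest p, of each list that passed camera or held 3 or more changed members, and the reported targets TNIP1, PTK2B, ARCN1 and PRKG1 with DICER1, ALB and AFP. Loci without a proper name were skipped. This gave 94 genes, 88 of them changed. Members named outside the rule, to complete a count or because they lie in a chromosome stretch, were chosen after their values were seen; these are CXCL8, NFKBIA, BST2, the probe set shared by MIR519A2 and MIR517C and the changed genes of lists that did not pass and held 1 or 2 of them.

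Alternatives fixed beforehand were the replicate number as a block, leaving out each array, quantile and cyclic loess normalization, median centring, filters on dim probe sets at the median and the 25th percentile, the mean of a gene's probe sets, every probe set by itself, an intensity trend with a robust prior, array weights, a minimum change of 1.5-fold and a test without moderation. Added after the data were seen were the fit over probe sets of the annotation table only, a separation of listed and unlisted probe sets in the variance prior, the fits without the genes of the chromosome stretches, and the list tests after both normalizations. Stretches of neighbouring genes were searched in windows of 31 genes, with 1000 shuffles of gene order over the genome. The limits of the stretches on chromosomes X and 12 are those of the run of at least 10 bright genes with the strongest contrast to the rest of its chromosome. Limits taken from the middle genes of the windows above the shuffles were RPSAP15 to RTL8A (98 bright genes) and TBC1D15 to NAA25 (130 bright genes). Among others, TSPAN8, LGR5, OAS1 and OAS3 lie outside these limits. The code was tested on simulated data made from these arrays' means and spread: among 18417 genes, 87 of 100 genes changed by 0.5 log2 units and 100 of 100 changed by 1 log2 unit were recovered, with 14 unchanged genes called, and camera recovered the shifted list and called 0 of 38 others. The simulated genes were drawn independently of each other, so these data could not show false list calls that arise from correlated genes. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used for the tables.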

Results

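Total RNA from Huh-7 cells, a line grown from a human hepatocellular carcinoma, was measured on 6 expression arrays. The cells had been transduced with a lentivirus made in 293T cells, an embryonic kidney line, and GFP-positive cells had been sorted by flow cytometry. For 3 arrays the vector carried the microRNA gene MIR517A together with GFP, and for 3 it carried GFP without the microRNA. MIR517A belongs to a large cluster of microRNA genes that is active mainly in the placenta. The arrays are named MIR517A 1 to 3 and GFP control 1 to 3 here. Each array held 33297 probe sets, of which 19460 matched 1 gene each and gave 18417 genes. Median intensities lay between 82.7 and 87.8 on the 6 arrays, and the number of arrays limits the precision. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which can be technical. No probe set was assigned to MIR517A or to GFP alone, so the level of the introduced microRNA was not analysed here. Of 7 probe sets for other microRNA genes of the cluster, 0 passed in the fit over every probe set. The lowest adjusted p, 0.21, belonged to the one shared by MIR519A2 and MIR517C, with means of 2.18 log2 units in the controls and 2.68 in MIR517A cells. Group means of all 7 lay between 1.98 and 3.40, below the 25th percentile of every array (4.78 to 4.90). The fit over every probe set also called few probe sets, 218 against 1108 with separate variance priors for listed and unlisted ones. A change of these microRNAs therefore stays open.

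The comparison of both groups asks which messenger RNAs differ in hepatoma cells that carry the microRNA vector. TNIP1, which encodes a ubiquitin-binding protein that restrains NF-kB signalling, had the largest fall among the genes eligible for naming, from 8.67 ± 0.12 log2 units in the controls to 7.95 ± 0.08 in MIR517A cells (SD, n = 3 each). It was 1.65-fold lower (adjusted p = 0.00367). ALDOC, a glycolytic aldolase best known from brain, was 1.61-fold lower (adjusted p = 0.00335), and LEFTY2, a secreted inhibitor of nodal signalling, was 1.51-fold lower (adjusted p = 0.0047). The next falls were those of SH3RF3, CNIH2, the microRNA gene MIR147A, the serine protease gene HTRA3, the flippase gene ATP10D, MYEF2, VPREB3, MYOZ3 and the creatine transporter gene SLC6A8, between 1.41-fold and 1.51-fold. TNIP1, ALDOC, LEFTY2, SH3RF3, HTRA3 and ATP10D passed with each of the 6 arrays left out in turn, whereas the other 6 did not.

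The largest rise was that of TSPAN8, which encodes a tetraspanin of epithelial cells, from 6.93 ± 0.41 log2 units in the controls to 8.26 ± 0.17 in MIR517A cells (SD, n = 3 each). It was 2.51-fold higher (adjusted p = 0.00634), and its adjusted p was 0.0503 without MIR517A 1. PALMD was 2.24-fold higher (adjusted p = 0.000789), and IL18, a cytokine of the interleukin-1 family, was 2.12-fold higher (adjusted p = 0.00229). CER1, a secreted antagonist of nodal and BMP ligands, was 2.05-fold higher, from 5.86 ± 0.01 to 6.90 ± 0.03 log2 units (adjusted p = 0.000789). Rises between 1.93-fold and 2.03-fold were measured for PDE5A, a phosphodiesterase of cyclic GMP, for SLFN11, a factor that blocks stalled replication forks, for FBN1, which encodes fibrillin-1, for KYNU, the kynureninase of tryptophan breakdown, and for GPX8, a peroxidase of the endoplasmic reticulum. KYNU lost its call without MIR517A 1 (adjusted p = 0.0539). DOCK11, RADX and MOSPD1, which rose by 1.95-fold, 1.89-fold and 1.88-fold, lie in a stretch of chromosome X whose genes were higher as a group, and TSPAN8 lies at the edge of such a stretch on chromosome 12, inside or outside it depending on how the limits are set.

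**Figure D1:**
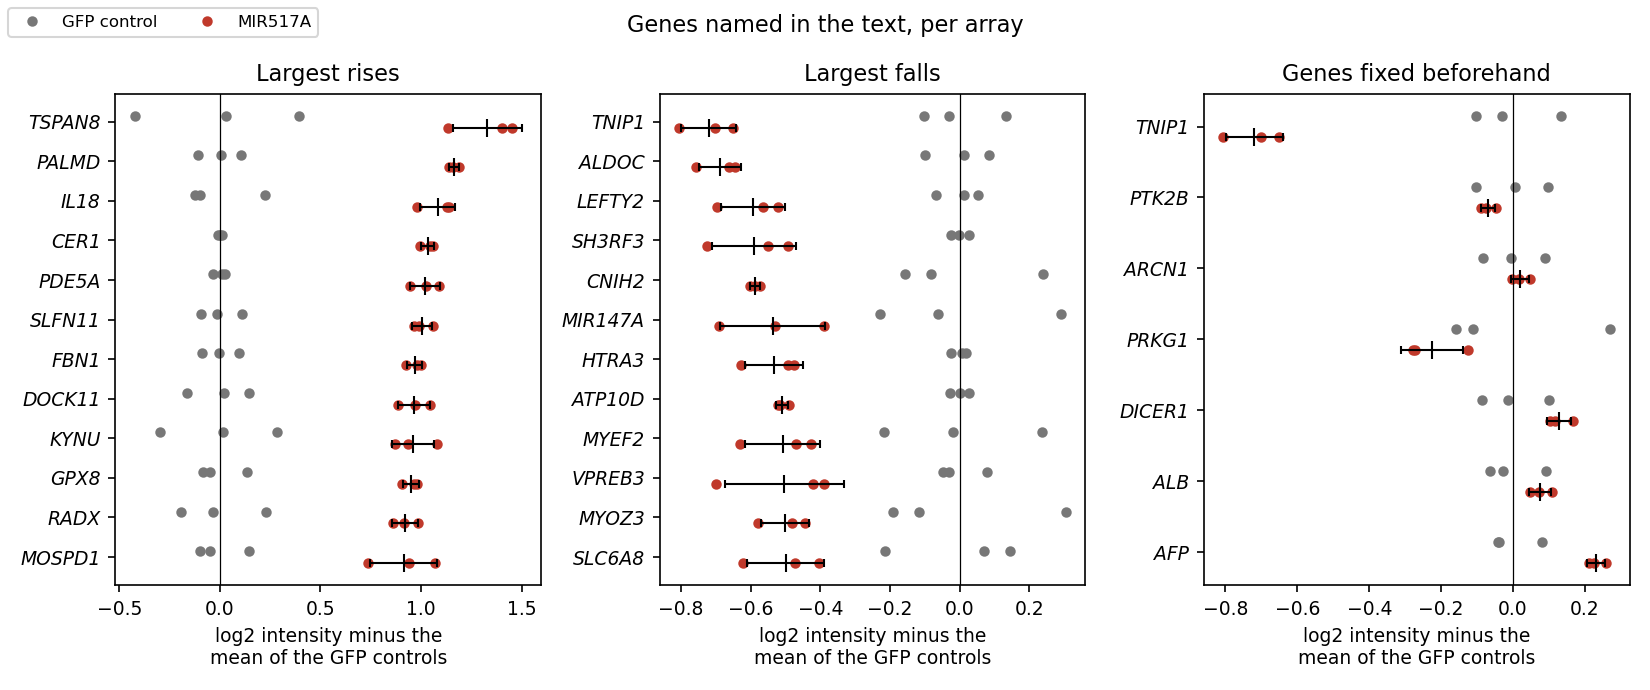
Log2 intensity of each array minus the mean of the 3 GFP controls (horizontal axis, log2 units) for the 12 genes with the largest rises, the 12 with the largest falls, both among genes eligible for naming, and the genes named whatever their p. Grey points are the GFP control arrays, red points the MIR517A arrays, and the black bar with whiskers is the MIR517A mean with its SD. In the first 2 panels the groups do not overlap, as the naming rule requires, while the MIR517A means of ARCN1 and PTK2B lie at 0.02 and -0.07.

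In all, 1978 of the 18417 genes passed an adjusted p of 0.05 in limma, 1264 of them higher and 714 lower in MIR517A cells. Most changes were small: 179 of these genes changed by 1.5-fold or more, 161 upwards and 18 downwards. The count and its split depended on the scaling, with 820 genes after quantile normalization (579 higher, 241 lower), 898 after cyclic loess normalization (687 higher, 211 lower) and 3654 with each array centred on its median (3045 higher, 609 lower). It also depended on single arrays: 947 genes passed without GFP control 1, 2289 without GFP control 2, 1092 without GFP control 3, 150 without MIR517A 1, 483 without MIR517A 2 and 263 without MIR517A 3.

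Among 4 genes reported in the literature as targets of miR-517a-3p or its near-identical relative miR-517c-3p, TNIP1 fell and the other 3 did not pass. PTK2B, a focal adhesion kinase, differed by -0.07 ± 0.07 log2 units (SE, n = 3 each; adjusted p = 0.508), and PRKG1, the cyclic GMP-dependent kinase, by -0.23 ± 0.12 (adjusted p = 0.192). ARCN1, a coat protein of COPI vesicles, differed by 0.02 ± 0.07 (adjusted p = 0.853), and this difference was below 0 after quantile and cyclic loess normalization and without GFP control 1. The 4 genes as a list had a median of -0.15 (adjusted p = 0.128 in camera, and 0.442 with an estimated correlation). DICER1, which cuts microRNA precursors, differed by 0.13 ± 0.07 (adjusted p = 0.231). In limma, 0 of 17 genes of the microRNA machinery passed (1 at an unadjusted p under 0.05, 0 adjusted over the list alone, list median 0.08, adjusted p = 0.214), and 0 of 21 cytosolic ribosomal proteins (3 at an unadjusted p under 0.05, 0 adjusted over the list alone, list median 0.03, adjusted p = 0.562). Both medians turned below 0 after quantile normalization. The hepatic markers ALB and AFP differed by 0.08 ± 0.07 (adjusted p = 0.455) and 0.23 ± 0.07 (adjusted p = 0.059).

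Of 39 gene lists fixed before the data were examined, 13 passed camera with the preset correlation of 0.01, 11 of them towards higher and 2 towards lower levels. With an estimated correlation none passed (lowest adjusted p = 0.442), and 2 had an unadjusted p under 0.05. Of the list members named next, HPX, SERPINC1, APOA2, GPX2, NDUFA1, PECAM1, TNIP1, FBN1 and LUM passed with each array left out in turn, and the others did not. All 13 medians kept their sign after quantile normalization, cyclic loess normalization and median centring. In list tests added after the data were seen, however, only 5 of the 13 passed after quantile normalization, namely secreted hepatocyte proteins, drug metabolism, cholesterol biosynthesis, NF-kB targets and the ATF4 response, and 4 after cyclic loess normalization, the same without the secreted proteins. With each array left out in turn, secreted hepatocyte proteins, drug metabolism, cholesterol biosynthesis, G1/S, G2/M, the unfolded protein response and the ATF4 response passed in all 6 fits, the respiratory chain in 5, NRF2 targets in 4, NF-kB targets and endothelial markers in 3 each, histones in 2 and fatty acid oxidation in 1. Among genes above the median level of all probe sets, only cholesterol biosynthesis, NF-kB targets and the ATF4 response of the 13 passed. Because bright genes were higher as a class in MIR517A cells, the median of each passing list is also set against 10000 random lists matched on brightness. Genes of the random lists were drawn independently, so a percentile can look too extreme where list members are correlated. The estimated correlation was 0.23 for cholesterol biosynthesis, 0.10 for the ATF4 response, 0.10 for NF-kB targets and -0.02 for drug metabolism. Some lists that did not pass lay further out among their random lists than NRF2 targets (percentile 74.2) and G2/M (82.1), which passed. Interferon response genes stood at percentile 97.8, glycolysis at 0.01, the hypoxia response at 0.41, MAPK feedback genes at 0.62 and ribosomal proteins at 1.04.

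Cholesterol biosynthesis had the lowest adjusted p of the lists. Of its 17 measured genes, 8 rose and 0 fell, 14 rose adjusted over the list alone, and all 17 differences were above 0. Its median was 0.27 (adjusted p = 7.5e-06, and 0.442 with an estimated correlation), against 0.10 for random lists of the same brightness. INSIG1, an anchor that restrains sterol-regulated transcription, rose by 1.32-fold (adjusted p = 0.0157), HMGCS1, which makes HMG-CoA, by 1.31-fold (adjusted p = 0.0269), SQLE, squalene epoxidase, by 1.29-fold (adjusted p = 0.026), and NSDHL, a sterol dehydrogenase, by 1.24-fold (adjusted p = 0.0296). In the list of amino acid response genes driven by the transcription factor ATF4, 5 of 21 rose and 0 fell, with 10 rising adjusted over the list alone. The median was 0.20 (adjusted p = 0.000132, and 0.442 with an estimated correlation), at percentile 99.9 of the random lists. ASNS, asparagine synthetase, rose by 1.34-fold (adjusted p = 0.00926), VLDLR, a lipoprotein receptor, by 1.51-fold (adjusted p = 0.0102), AARS1, the alanyl-tRNA synthetase, by 1.28-fold (adjusted p = 0.0212), and ALDH1L2, a mitochondrial folate enzyme, by 1.51-fold (adjusted p = 0.0179). ALDH1L2 lies in the chromosome 12 stretch.

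Secreted hepatocyte proteins, drug metabolism and fatty acid oxidation also passed as higher, whereas liver transcription factors, bile acid genes and acute phase genes did not pass (adjusted p = 0.82, 0.491 and 0.813). Bile acid genes nevertheless had a median of 0.09 at percentile 98.3 of the random lists. Among 23 secreted hepatocyte proteins, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.13 (adjusted p = 0.00301, and 0.442 with an estimated correlation) at percentile 84.0 of the random lists. SERPINC1, which encodes antithrombin, rose by 1.60-fold (adjusted p = 0.00395), HPX, the heme carrier hemopexin, by 1.5-fold (adjusted p = 0.00386), APOA2, an apolipoprotein of HDL, by 1.42-fold (adjusted p = 0.0077), and ITIH2 by 1.29-fold (adjusted p = 0.017). Of 17 genes of drug and xenobiotic metabolism, 3 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.0192, and 0.442 with an estimated correlation) above all of the random lists. The sulfotransferase gene SULT2A1 was 1.55-fold higher (adjusted p = 0.0277), UGT2B4, a glucuronosyltransferase, 1.31-fold higher (adjusted p = 0.0293) and ADH6, an alcohol dehydrogenase, 1.28-fold higher (adjusted p = 0.0427), while the cytochrome CYP1A2 was 1.35-fold lower (adjusted p = 0.0266). Fatty acid oxidation had 5 risen and 0 fallen genes of 16 (5 and 0 adjusted over the list alone) and a median of 0.15 (adjusted p = 0.046, and 0.442 with an estimated correlation) at percentile 92.9. HADHB and HADHA, both subunits of the mitochondrial trifunctional protein, rose by 1.41-fold and 1.28-fold (adjusted p = 0.0201 and 0.0235). They are neighbours on chromosome 2, where HADHA ends a run of 15 bright genes that were higher as a group (median 0.35). ACAA2 and the carnitine carrier SLC25A20 rose by 1.25-fold and 1.24-fold.

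Other lists passed with few changed members. In G1/S and DNA replication only CCNE2, cyclin E2, rose among 24 genes (1 adjusted over the list alone; 1.24-fold, adjusted p = 0.0303), with a list median of 0.17 (adjusted p = 0.00698) at percentile 96.6. In G2/M and mitosis the kinetochore genes CENPE and NUF2 rose by 1.21-fold and 1.26-fold among 24 (8 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.00161) at percentile 82.1. EDEM1, a factor that clears misfolded glycoproteins, was the only riser among 18 genes of the unfolded protein response (0 adjusted over the list alone; 1.21-fold, adjusted p = 0.0406; list median 0.16, adjusted p = 0.0077, percentile 92.3). GPX2, a glutathione peroxidase, and SLC7A11, the cystine transporter, rose by 1.54-fold and 1.37-fold among 17 targets of NRF2 (3 adjusted over the list alone; list median 0.11, adjusted p = 0.0401, percentile 74.2). NDUFA1, a gene of the chromosome X stretch, and COX4I1 rose by 1.51-fold and 1.20-fold among 21 genes of the respiratory chain (3 adjusted over the list alone; list median 0.14, adjusted p = 0.026, percentile 87.4). In limma, 0 of 11 histones passed (3 at an unadjusted p under 0.05, 0 adjusted over the list alone), and their median was 0.15 (adjusted p = 0.0413, percentile 81.9). With an estimated correlation the adjusted p of the histones was 0.568 and that of the other lists of this paragraph 0.442.

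The 2 lists that shifted downwards were targets of NF-kB and endothelial markers. Among 20 targets of NF-kB, TNIP1 and the chemokine gene CXCL1 fell and 0 rose (3 fell adjusted over the list alone), and CXCL1 was 1.28-fold lower (adjusted p = 0.0223). The list median was -0.09 (adjusted p = 0.0412, and 0.442 with an estimated correlation), below every random list, whose middle value was 0.06. CXCL8 and NFKBIA did not pass, with differences of 0.18 and -0.09 log2 units. Among 11 endothelial markers, the angiopoietin receptor gene TEK and the scavenger receptor gene STAB2 were 1.28-fold and 1.21-fold lower, and PECAM1 was 1.60-fold higher (adjusted p = 0.026, 0.0403 and 0.00607; 3 fell and 1 rose adjusted over the list alone). The list median was -0.21 (adjusted p = 0.026, and 0.442 with an estimated correlation) at percentile 3.00. Its median level was 5.09 log2 units, below the median gene at 6.98, and STAB2 lies in the chromosome 12 stretch. In limma, 0 of 9 markers of the 293T packaging cells passed (2 at an unadjusted p under 0.05, 0 adjusted over the list alone, list median -0.17, adjusted p = 0.0707). The 293T list had a median level of 5.39 log2 units and stood at percentile 24.0 of its random lists, whose middle value was -0.13. Among 12 fibroblast markers FBN1, LUM and PDGFRA rose and COL6A3 fell (3 and 4 adjusted over the list alone, list median -0.12, adjusted p = 0.706), and among 13 immune markers CD14 rose and CD3E and CD2 fell (1 and 2 adjusted over the list alone, list median -0.13, adjusted p = 0.087). LUM was dim, at 3.31 log2 units in the controls and 4.15 in MIR517A cells.

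**Figure D2:**
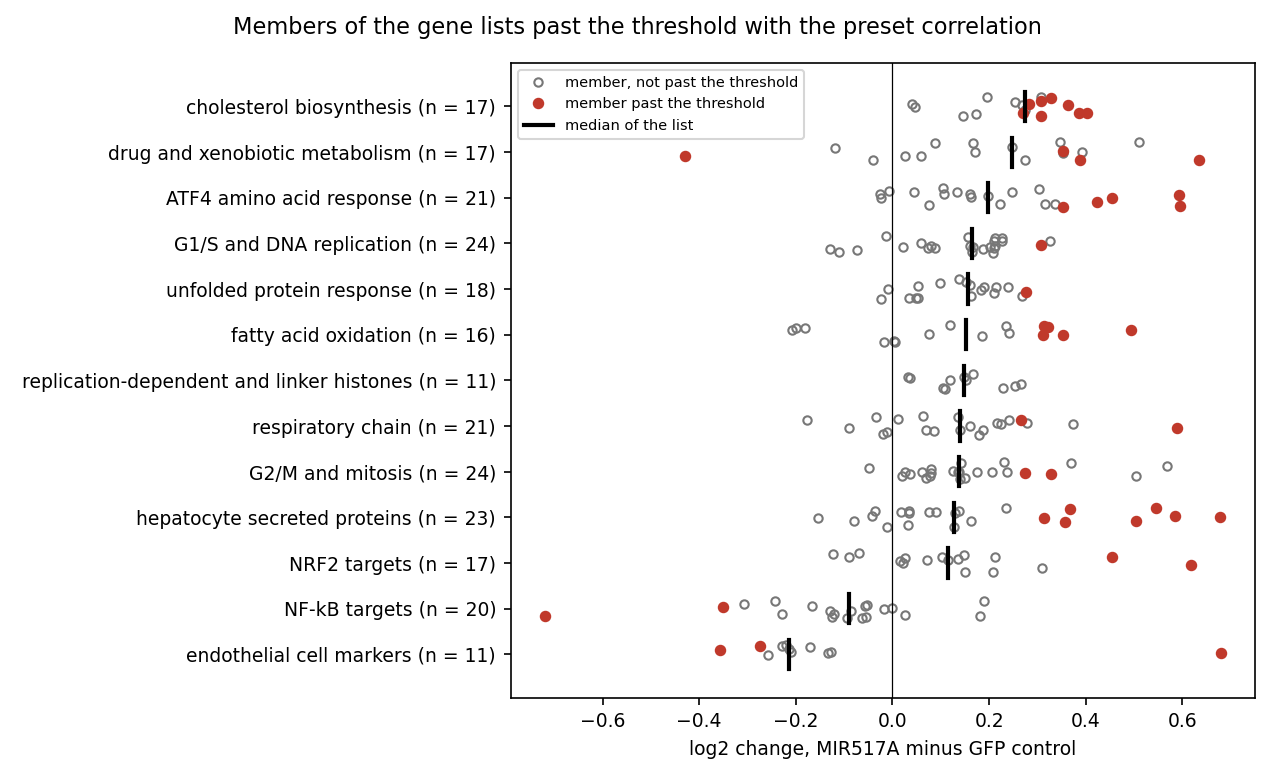
Log2 change of each measured member (horizontal axis, MIR517A minus GFP control) for the 13 lists past the threshold with the preset correlation. Filled red points passed an adjusted p of 0.05 over all genes, open points did not, and the black bar is the list's median, which runs from 0.27 for cholesterol biosynthesis to -0.21 for endothelial markers.

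Changed genes were not spread evenly over brightness. Of the 714 genes that were lower, 606 (84.9%) lay in the dimmer part of the genes below the median level, and of the 1264 that were higher, 974 (77.1%) lay in the brighter part above it. The median change was -0.12 in the dimmest decile of genes and 0.11 in the brightest decile, a gap of 0.22 that was 0.08 after quantile and 0.03 after cyclic loess normalization. Under both normalizations 52 of the 88 named genes past the threshold still passed, TNIP1, ALDOC, TSPAN8 and CER1 among them.

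**Figure D3:**
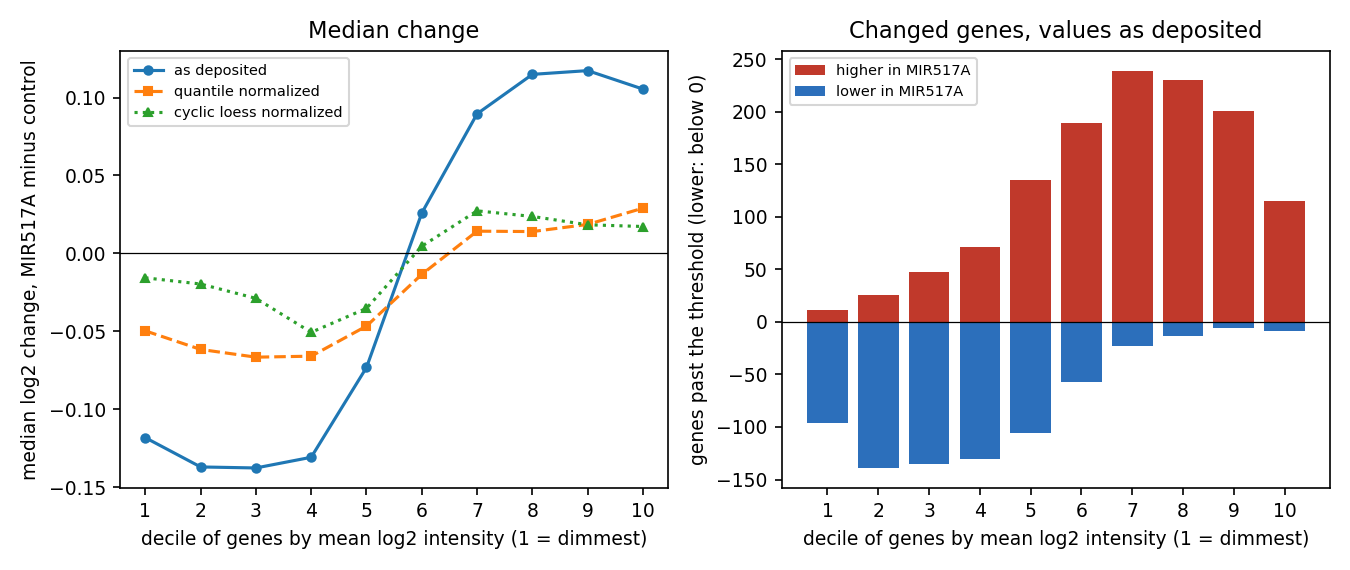
Left, median log2 change of genes (MIR517A minus GFP control) in deciles of mean log2 intensity, for the deposited values and after 2 normalizations. Right, genes past the threshold per decile, with genes lower in MIR517A drawn below 0. The medians of the deposited values lie between -0.14 in decile 3 and 0.12 in decile 9, and most lower genes sit in the dimmer deciles.

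Position on the chromosomes was examined after the gene results had been seen, with gene order from the GRCh38.p14 reference table and only genes brighter than the median probe set. On chromosome X, 100 bright genes from TSPAN6 to HTATSF1 had a median change of 0.49 (1.41-fold, 93 of them above 0), and the 207 other bright genes of the chromosome had 0.08. On chromosome 12, 140 bright genes from TSPAN8 to OAS3 had a median change of 0.31 (1.24-fold, 127 above 0), and the other 459 had 0.06. Measured per array against the control mean, the X stretch stood at 0.54, 0.50 and 0.47 on the MIR517A arrays and between -0.03 and 0.03 on the controls. The chromosome 12 stretch stood at 0.34, 0.29 and 0.28, against -0.03 to 0.05. Both medians stayed above 0 under each scaling, at 0.43 and 0.23 after quantile normalization. Without the genes of both stretches, 1546 of 18012 genes and 12 lists passed, and the endothelial markers did not. Leaving genes out also changes the variance prior and the adjustment, so the drop does not count the changed genes inside the stretches.

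**Figure D4:**
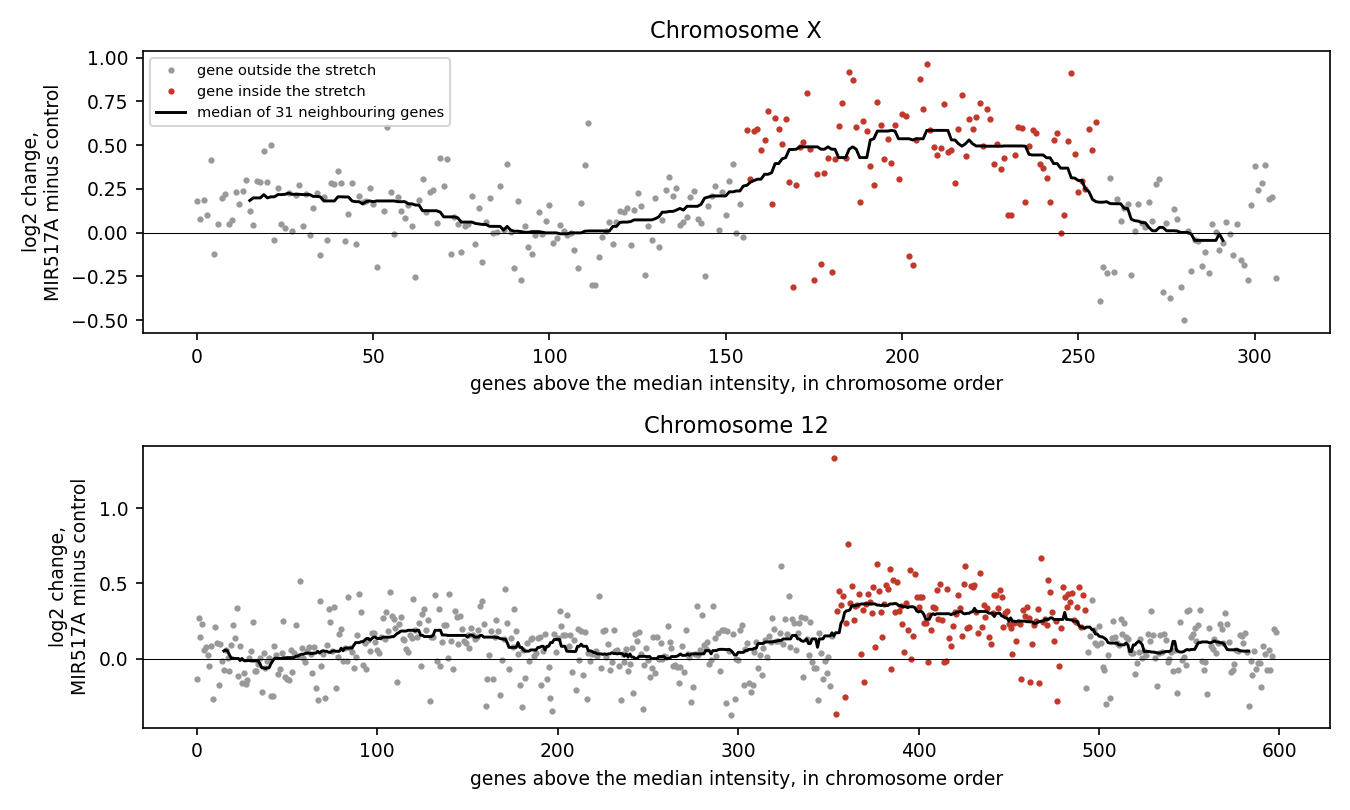
Log2 change of genes above the median intensity (vertical axis, MIR517A minus GFP control) in their order along chromosomes X and 12. Red points lie in the stretches from TSPAN6 to HTATSF1 and from TSPAN8 to OAS3, grey points outside, and the black line is the median of 31 neighbouring genes, which reaches 0.58 on chromosome X and 0.37 on chromosome 12.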

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

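These values come from the planned fit over every probe set, and looking at the unnamed probe sets separately was chosen only after that fit had been seen. The signals lie outside the gene-level comparison, in the 12083 probe sets that the annotation table does not list. Control probe sets of the array were not told apart and can be among them. Among them 28 were higher and 21 lower in MIR517A cells at an adjusted p under 0.05 (limma over all 33297 probe sets), and 2204 had an unadjusted p under 0.05. The 3 largest rises were those of probe set 7892682, by 1.95 log2 units from 2.36 ± 0.19 to 4.31 ± 0.13 (SD, n = 3 each; adjusted p = 0.0152), probe set 8155248, by 1.83 (adjusted p = 0.0237), and probe set 7894616, by 1.43 (adjusted p = 0.0372). Larger than any change of a named gene, probe set 7894600 fell by 3.07 log2 units, from 6.29 ± 0.36 to 3.22 ± 0.51 (adjusted p = 0.0269). The 3 that rose lay below the 25th percentile of every array (4.78 to 4.90) in both groups, and probe set 7894600 lay below it in MIR517A cells. Background was not measured, so the size of these changes is uncertain. What these probe sets measure was not analysed here, and no biological explanation was tested.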

How the results depend on the processing

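All alternatives were planned except the fit over listed probe sets (1886 genes), those without the chromosome stretches (1546 genes, 12 lists), the list tests after normalization and the fits with separate priors. Against 1978 genes, the count was 820 after quantile normalization, 898 after cyclic loess normalization, 3654 with median centring, 218 with every probe set tested (80.7% higher), 179 with a 1.5-fold minimum (89.9% higher) and 202 without moderation (78.2% higher); it lay between 1994 and 2723 with the mean of probe sets, both brightness filters, the trend and array weights (78.8% higher among genes above the median level, against 63.9%). The fall to 218 came mainly from the variance prior shared with the unlisted probe sets, because adjusting the same p-values over listed probe sets alone gave 243, whereas separate priors adjusted over all probe sets gave 1108. Leaving out 1 array gave 150 to 2289 genes and 9 to 14 lists, and 88.7%, 76.8% and 82.1% were higher without MIR517A 1, 2 and 3. Replicate numbers did not pair the arrays (correlations of same-numbered deviations 0.05, -0.15 and -0.09), and the fit with the replicate block called 1009 genes, 945 of them shared, and 11 lists. Against 13 lists, 0 passed with an estimated correlation, 4 among genes above the median level (3 of them among the 13), 7 after quantile (5 of the 13) and 6 after cyclic loess normalization (4 of the 13). The 14 lists without GFP control 3 hold 10 of the 13, and glycolysis, fatty acid synthesis, YAP targets and 293T markers besides. Cholesterol biosynthesis and the ATF4 response passed in every setting but the estimated correlation. The log2 change of ARCN1, which did not pass, reversed to -0.0555 after quantile and -0.0724 after cyclic loess normalization and lay between -0.0217 (without GFP control 1) and 0.0645 (without GFP control 3) with 1 array left out; AFP passed in 6 settings. No other named gene changed sign. Of the 88 named genes that passed, 27 did so with every array left out and 9 in all settings that tested them, ALDOC, CER1, PALMD, PDE5A, SLFN11, FBN1, GPX8, GPX2 and ANKRD1. Where not stated, the cause was not tested. The site and RNA quality tests were not run, and signal over background was not measured.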

Other observations

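Of the tests in this part, those of lists under other scalings, of splits of the arrays, of chromosome stretches, of brightness, of gene density and of TNIP1 over listed probe sets, with separate priors and without the stretches were chosen only after the results had been seen. Several gene groups that did not pass as lists held changed members. Of those named next, HP, ANKRD1, PHLDA1, EREG, FBN1, LUM and ALDOC passed with each array left out in turn, and the other genes covered by the naming rule did not. Among 16 oncofetal and progenitor genes, 4 rose and 0 fell (5 and 1 adjusted over the list alone), SPP1, which encodes osteopontin, by 1.83-fold (adjusted p = 0.00687), the surface marker EPCAM by 1.53-fold, PROM1, which encodes CD133, by 1.4-fold and the RNA-binding protein gene IGF2BP3 by 1.34-fold (list median 0.09, adjusted p = 0.214). Of 16 targets of YAP, ANKRD1 rose by 1.61-fold (adjusted p = 0.00292), NT5E by 1.30-fold, CRIM1 by 1.28-fold and CCN1 by 1.24-fold (4 rose and 1 fell adjusted over the list alone, list median 0.10, adjusted p = 0.0683). EREG, a ligand of the EGF receptor, rose by 1.61-fold (adjusted p = 0.00444), IGFBP3 by 1.28-fold and EGFR itself by 1.20-fold among 22 growth factor genes (4 and 1 adjusted over the list alone, list adjusted p = 0.719). Among immediate early and feedback genes of MAPK signalling, PHLDA1 and DUSP4 rose by 1.4-fold and 1.33-fold and FOSL1 was 1.27-fold lower (2 and 1 adjusted over the list alone, list adjusted p = 0.995); PHLDA1 lies in the chromosome 12 stretch. The acute phase genes HP and FGL1 rose by 1.82-fold and 1.75-fold and IL1RN was 1.37-fold lower (2 and 2 adjusted over the list alone, list adjusted p = 0.813). Of 24 interferon response genes, IFIT3 rose by 1.55-fold, OAS1 by 1.34-fold, the RNA sensor gene RIGI by 1.26-fold and OAS3 by 1.25-fold, and BST2 was lower (4 and 1 adjusted over the list alone, list adjusted p = 0.557); OAS1 and OAS3 lie at the end of the chromosome 12 stretch, in or out of it by how the limits are set. Among p53 targets SESN1 and GDF15 rose by 1.29-fold and 1.22-fold and MDM2 was 1.21-fold lower (6 and 2 adjusted over the list alone, list adjusted p = 0.234).

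CDH1, which encodes E-cadherin, rose by 1.26-fold (adjusted p = 0.0233) and CLDN3 was 1.24-fold lower among 16 junction genes (2 and 1 adjusted over the list alone, list adjusted p = 0.818). SPARC rose and S100A4 fell among 17 mesenchymal genes (2 and 1 adjusted over the list alone, list adjusted p = 0.935), and CD44 rose and ITGB4 fell among 21 proteases and integrins (3 and 1 adjusted over the list alone, list adjusted p = 0.557). Of 12 fibroblast and stellate cell markers, FBN1 rose by 1.96-fold, LUM, in the chromosome 12 stretch, by 1.79-fold and PDGFRA by 1.26-fold, and COL6A3 was 1.27-fold lower (3 and 4 adjusted over the list alone, list adjusted p = 0.706). The means of LUM, 3.31 log2 units in the controls and 4.15 in MIR517A cells, lay below the 25th percentile of every array (4.78 to 4.90). The size of its change is therefore uncertain. CD14, which hepatocytes also express, rose by 1.31-fold among 13 immune markers, and CD3E and CD2 were 1.33-fold and 1.21-fold lower (1 and 2 adjusted over the list alone, list adjusted p = 0.087). COL6A3, CD3E and CD2 were dim, with group means between 4.54 and 5.23 log2 units, and dim genes fell as a class. The apoptosis inhibitors XIAP, in the chromosome X stretch, and BIRC2 rose among 17 apoptosis regulators (4 and 0 adjusted over the list alone, list adjusted p = 0.117), TNFRSF19 rose and LGR5 fell among 17 Wnt targets (4 and 3 adjusted over the list alone, list adjusted p = 0.678), and LPIN1 rose among 18 genes of fatty acid synthesis (4 and 0 adjusted over the list alone, list adjusted p = 0.0864). LGR5 lies at the edge of the chromosome 12 stretch, in or out of it by how the limits are set. Glycolysis (ALDOC lower, also adjusted over the list alone, list median -0.07, adjusted p = 0.087) and the hypoxia response (PFKFB4 lower, also adjusted over the list alone, list median -0.05, adjusted p = 0.225) did not pass over all deposited values, passed as lower after quantile and cyclic loess normalization, and had medians of 0.02 with median centring. Glycolysis also passed as lower among genes above the median level and without GFP control 3. These calls use the preset correlation; with an estimated correlation the adjusted p of both lists was 0.442 on the deposited values. Liver transcription factors, bile acid genes, heat shock genes, metallothioneins and TGF-beta targets held 0 changed genes in limma, over all genes and adjusted over the list alone, and 2, 4, 1, 1 and 4 at an unadjusted p under 0.05 (list adjusted p of 0.82, 0.491, 0.466, 0.274 and 0.565). Median, mean and test differed in sign for liver transcription factors, acute phase genes, proteases and integrins, Wnt targets and fibroblast markers.

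With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 1978 genes and the highest other split 0, so only the real split among the 10 gave as many genes. The real split called 13 lists against 8 in the highest other split, and again only the real one gave as many. The other splits passed 0, 8, 6, 1, 6, 8, 1, 4 and 1 lists while calling 0 genes. Camera at the preset correlation thus also passed lists between groups that mixed MIR517A and control arrays, which limits the weight of the 13 lists.

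Chromosomes X and 12 held the highest windows of neighbouring genes. Chance is argued against for both, since these windows reached 0.58 and 0.366 and the highest of 1000 shuffles 0.279. The same held for chromosomes 7, 4 and 6 (0.296, 0.288 and 0.287). Many other stretches passed the 95% limits of the shuffles, in both directions. Higher ones include 15 bright genes from UBXN2A to HADHA on chromosome 2 (median 0.35) and 77 from ACADM to CDC14A on chromosome 1 (0.26). Lower ones include 44 bright genes from RASSF7 to CDKN1C on chromosome 11 (median -0.19) and 49 from FCN2 to TUBB4B on chromosome 9 (-0.12). KYNU and ADH6 lie at the ends of higher stretches. Which other named genes lie inside such stretches was not listed, so their changes cannot be taken as separate from regional shifts. A general rise of gene-poor regions is argued against for chromosome X, where the 95% bootstrap interval of the median starts at 0.448 and the highest other window as gene-poor reached 0.296, and stays open for chromosome 12, where the interval starts at 0.279. The other windows leave out those that touch either stretch. Both intervals can be too narrow, because the limits were set from these same changes and neighbouring genes were resampled as if independent. An added copy of the X stretch in the sorted MIR517A cells stays open: the 9 probe sets of the stretch that were not used to find it had a median of 0.586, which any cause that acts on the whole region would give. The 98 genes of the stretch below the median level had a median of -0.09, against -0.12 to -0.14 in deciles 1 to 4 of all genes. Dim probe sets keep a floor of unspecific signal, so this value cannot decide for or against an added copy. Copy number was not measured, regional regulation was not tested, and an effect of the microRNA cannot be separated from a difference between the transduced populations.

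Dim genes fell and bright genes rose. Whether a technically wider spread of intensities on the MIR517A arrays lies behind this stays open: the gap between the brightest and dimmest decile went from 0.22 to 0.0787 with quantile normalization, but giving all arrays the same distribution shrinks such a gap whatever its cause. Olfactory receptor genes, 361 genes with little expected expression in liver cells, had a median of -0.15 (-0.07 after quantile and -0.04 after cyclic loess normalization), and 27 of them were called lower and 1 higher. Their median differed from that of other genes of the same brightness by -0.0309 (95% bootstrap interval -0.0652 to 0.0035), which any shift that depends on brightness alone would give, so signal of unexpressed genes stays open as well. A biological part of this shift also stays open.

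Outside both stretches, genes in gene-dense regions were lower against genes in gene-poor regions. Over 335 windows of 31 bright genes the median change had a Spearman correlation of -0.754 with gene density (permutation p = 0.0001, the smallest that the permutations can give), from 0.17 in the gene-poorest class to -0.01 in the densest; windows are not independent replicates. Arrays of the same group differed along the same axis, and the difference between GFP control 3 and GFP control 2 correlated with gene density at 0.705, so a technical difference between arrays, such as RNA quality or labelling, could produce the trend. All 3 MIR517A arrays lie on 1 side and all controls on the other (correlations of -0.66 to -0.76 against 0.31 to 0.75 over the same 335 windows, each array against the mean of the 6), which leaves a group effect open.

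TNIP1, the reported target that fell, changed by between -0.81 and -0.65 log2 units over all alternatives, and it missed the threshold only without moderation (adjusted p = 0.057). Target sites in its transcript were not searched, and the level of the microRNA was not measured.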
